A study of Homo sapiens with 40 samples.

How the data were processed

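Total RNA of A549 cells, an established human lung carcinoma line, was labelled with Cy3 and hybridised to 40 Illumina expression arrays. Per the labels, the cells were transfected with siRNA against CCAR1, CoCoA (gene CALCOCO1), CCAR2 or ZNF282, or with a nonspecific siRNA (siNS). They were moved to hormone-free medium 2 days after transfection and given 100 nM dexamethasone (dex) or ethanol for 6 h on the next day. The titles of the ethanol arrays carry a time of 0 h, while the protocol text gives ethanol for the same 6 h; the groups were taken as ethanol controls. The 5 siRNAs and both treatments made 10 groups: siNS held 6 arrays per treatment, siCCAR1, siCoCoA and siCCAR2 held 4 each, and siZNF282 held 2.

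The deposited values were log2 probe intensities that had already been normalized between arrays; the authors named limma 3.14.4, and their background correction, normalization and probe filter are not stated in the labels. The log base was taken from the range of the values, 4.13 to 14.3, with array medians of 4.67 to 4.69. Correlations between pairs of arrays over all probes ran from 0.948 to 0.993. The number of arrays limits the precision of every value. A table of non-normalized signals was used only for its 48107 probe IDs, which held all 34469 probes of the normalized table. Its 80 columns for samples (40 of signal and 40 of detection p) are named by chip position, which no label pairs with a sample, and were not used here. The plan had been to start from those signals and to filter on detection p; the deposited log2 values, which had been listed as an alternative start, were used in their place, with a filter on intensity.

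Of the probes, 26360 carried 1 gene symbol in the platform annotation, 3 carried several, and 8106 were not listed there; the last 2 kinds were left out. A probe was kept when its mean was above 5 on the log2 scale in at least 1 group (the most frequent value of all arrays was 4.39), which left 13903 probes. Each gene was represented by its brightest probe, giving 10608 genes, of which 2672 had more than 1 probe above the line. Genes are called near background where a group mean lay below that line. Array values carry no coordinates and no genome build was used.

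A mean per group was fitted to all 40 arrays with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with 30 residual and 5.86 prior degrees of freedom. Tests were 2-sided, p-values were adjusted with the Benjamini-Hochberg method over the 10608 genes, and an adjusted p under 0.05 was called. The 17 comparisons were dex against ethanol for each of the 5 siRNAs, each depletion against siNS in ethanol and in dex, and the difference between the dex response of each depletion and that of siNS. The p-values measure the spread between arrays; whether the arrays came from separate cultures is not stated in the labels, so this spread may be partly technical. The size of the dex response was compared over genes that the mean dex response of the other 3 depletions marked as changed (adjusted p under 0.05 and at least 1.5-fold). Each gene was counted as positive in the direction of that response. The difference between depleted and siNS cells was tested over these genes with fry of limma, which asks whether the set moved one way on balance.

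Before the data were examined, 24 gene lists were written from general knowledge, together with the comparisons, the tests, the rule for named genes and most of the alternatives. The lists were GR induced genes, inflammatory genes, metallothioneins, glucose and lipid metabolism, the circadian clock, ion and water transport, alveolar type II markers, the cell cycle, p53 targets, apoptosis regulators, Wnt targets, interferon-stimulated genes, nuclear receptors and coregulators, sterol synthesis, ER and amino acid stress, matrix and mesenchymal genes, NRF2 targets, hypoxia, ribosomal proteins, housekeeping genes, immediate early and RNA decay genes, and markers of endothelial cells, leukocytes and fibroblasts. The 21 lists with at least 5 tested genes were tested against the other genes with camera of limma, at its preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a comparison. Of the 357 list tests, 101 were called at the preset correlation and 41 of these held with an estimated correlation.

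The rule for named genes took, among called genes, the 12 largest rises and 8 largest falls of the siNS dex response; the 6 largest rises and falls of each depletion in dex and the 3 of each in ethanol; the 4 largest of each sign among the differences in dex response; the 4 largest rises and falls of each depletion among genes that dex had changed at least 2-fold in siNS cells; the 4 siRNA targets and NR3C1; up to 4 called members of each list described; and up to 8 genes called in the same direction by all 4 depletions. Targets were left out of all parts but their own, and a gene named for a comparison is given with its values in others where these bear on it.

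Whether arrays with the same number form pairs was checked on the residuals of the fit. Arrays with the same number in different groups had a mean correlation of 0.172 across genes, against −0.0451 for different numbers, and all 20 pairs of an ethanol and a dex array of the same siRNA were above 0.1 (0.127 to 0.470), so the fit was repeated with the replicate number as a fixed block. A paired value is printed beside a result only where it changes the call or moves a count more than 1.5 times.

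The other alternatives were no filter, the mean of a gene's probes, a fit of the compared groups only, arrayWeights of limma, and leaving out each array in turn. After the data were seen, 5 more were added: a filter line of 6 (8421 genes), arrays centred on the median of the tested genes, only the arrays numbered 2 and 3 (which gives each group 2 arrays), leaving out the arrays numbered 1, and leaving out both siNS arrays numbered 5. Not run, because the signals could not be given to samples, were fits without background correction, median scaling of the signals, the detection filter and a block for the chip.

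The overlap of called genes was set against arrays simulated with a shared siNS group (100 draws), against the number that independent calls would give, and against 20 ways of dividing the siNS dex arrays so that each comparison had 3 of its own. The fits were tested on simulated data, in which 50 genes at each of 4 sizes were changed in residual arrays (40 draws). Of genes changed 2-fold, 93.9% were called in a comparison of 4 depleted arrays with siNS, and 81.6% with 2. For a difference in dex response of the same size these shares were 72.0% and 51.0%. Of genes changed 1.5-fold, 58.3%, 36.7%, 25.0% and 12.4% were called, in the same order. The mean share of false calls was 4.38%, 8.52%, 5.87% and 10.95%, and single draws reached 108, 128, 137 and 524 false calls. In 1 simulated comparison camera at the preset correlation called the raised list and 1 further list. The size test gave 80.5% for a response set to 80%. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.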

Results

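Gene expression was measured on 40 arrays of A549 lung carcinoma cells, in which the glucocorticoid receptor (GR, gene NR3C1) mediates the response to dexamethasone (dex), a synthetic glucocorticoid. Cells held nonspecific siRNA (siNS, 6 arrays in ethanol and 6 in 100 nM dex for 6 h) or siRNA against 1 of 4 GR coregulators: siCCAR1, siCoCoA and siCCAR2 (4 and 4 arrays each) and siZNF282 (2 and 2). The number of arrays limits the precision. Values are log2 fold changes ± SE of the limma fit, the group sizes are those just given, and p-values are adjusted over 10608 genes.

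The first question was whether each siRNA lowered its own transcript. CCAR2, a nuclear protein also known as DBC1, was lower in siCCAR2 cells by −2.31 ± 0.14 in ethanol (adjusted p = 3.20e-14) and −2.30 ± 0.14 in dex (adjusted p = 6.92e-14), which left 20.1% and 20.3% of the siNS level. ZNF282, a zinc finger protein, was lower in siZNF282 cells by −1.42 ± 0.26 (adjusted p = 7.07e-05, 37.4% left) and −0.85 ± 0.26 (adjusted p = 0.0126, 55.5% left). CCAR1, a Mediator-binding coactivator, was lower in siCCAR1 cells by −0.72 ± 0.19 (adjusted p = 0.0080, 60.5% left) in ethanol and fell by 1.00 ± 0.19 (adjusted p = 1.90e-04, 49.8% left) in dex. CALCOCO1, which encodes CoCoA, was lower in siCoCoA cells by −0.44 ± 0.14 (adjusted p = 0.026, 73.8% left) and −0.88 ± 0.14 (adjusted p = 9.22e-06, 54.3% left). The probes were ILMN_1804789 for CCAR2, ILMN_1668185 for ZNF282, ILMN_1679127 for CCAR1 and ILMN_1774427 for CALCOCO1. CCAR2 also fell in siCoCoA cells, to 51.5% in ethanol (−0.96 ± 0.14, adjusted p = 7.63e-06) and 46.7% in dex (−1.10 ± 0.14, adjusted p = 4.06e-07). CALCOCO1 was higher in siCCAR1 cells in ethanol (0.50, adjusted p = 0.011) and in siZNF282 cells in ethanol (0.53, adjusted p = 0.019) and dex (0.66, adjusted p = 0.0037). NR3C1 was not called in any of the 8 depletion comparisons, with values of −0.40 to −0.01. CCAR1 in siCCAR1 dex cells and CALCOCO1 in siCoCoA cells were near background, which limits the falls that the array can show. CCAR1 read 4.60 on siNS dex array 4 and 5.66 to 6.10 on the other siNS dex arrays, and CALCOCO1 read 5.00 on siCoCoA ethanol array 1 and 4.68 to 4.73 on the others. The CALCOCO1 fall in ethanol was lost without any 1 of 6 arrays (siCoCoA ethanol arrays 2, 3 and 4 and siNS ethanol arrays 1, 2 and 3, −0.37 to −0.42), and the ZNF282 fall in dex was lost without either siZNF282 dex array (−0.82 and −0.88).

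**Figure D1:**
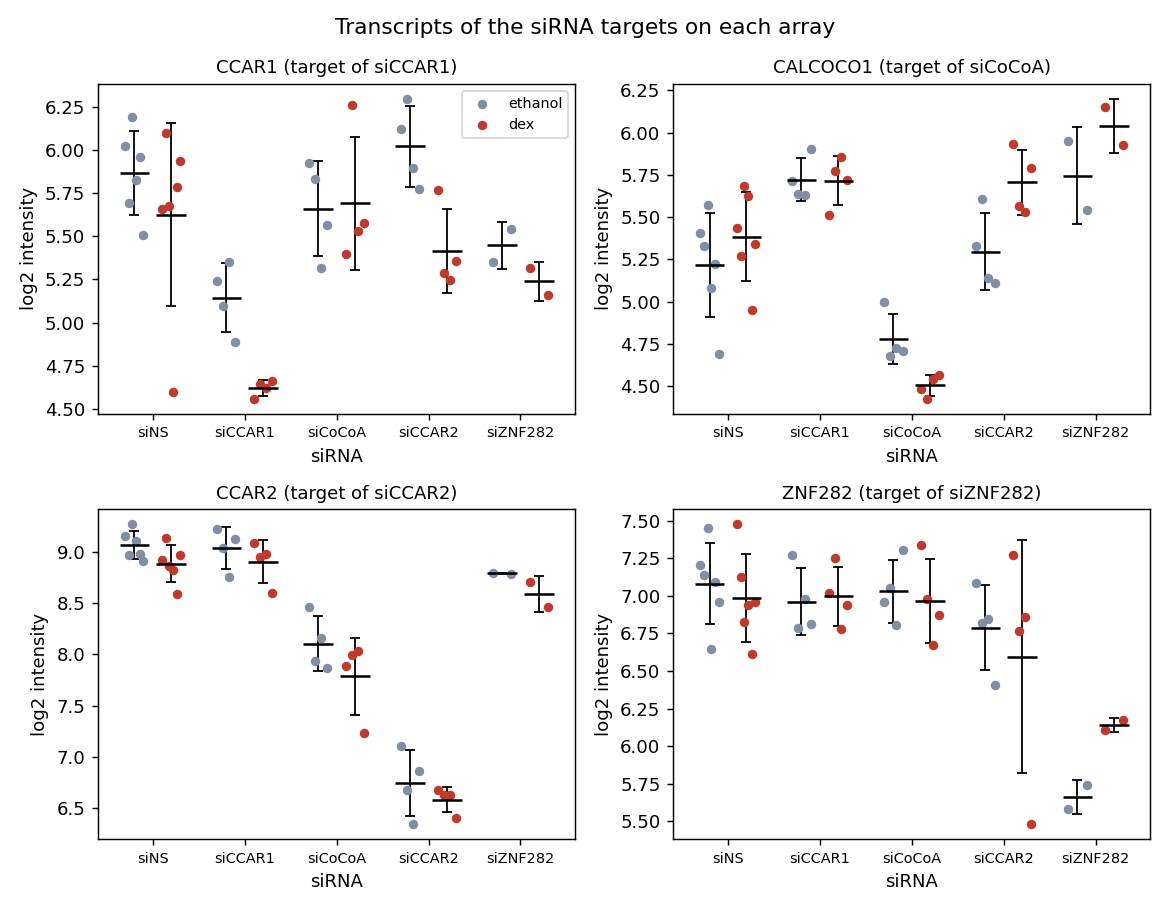
Log2 intensity of CCAR1, CALCOCO1, CCAR2 and ZNF282 in the 10 groups of siRNA and treatment; points are arrays, lines are group means and bars are the SD. Mean CCAR2 intensity was 9.06 in siNS and 6.75 in siCCAR2 cells in ethanol.

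The dex response of siNS cells gave the set of genes on which the coregulators could act. The largest rises were in CIDEC, a lipid droplet protein (4.26 ± 0.29, adjusted p = 2.66e-14, 19.1-fold), TSC22D3, the anti-inflammatory protein GILZ (3.95 ± 0.15, adjusted p = 3.33e-21), and DUSP1, a phosphatase that switches off MAP kinases (3.44 ± 0.12, adjusted p = 9.74e-23). SYBU rose by 3.21 ± 0.19 and ANGPTL4, an inhibitor of lipoprotein lipase, by 3.20 ± 0.20. Apart from MT1H and MT1G, given with their list below, next came BEST2 (3.08 ± 0.15), ETNK2 (2.96 ± 0.18) and FBXL16 (2.87 ± 0.20). The transcription factor KLF9 rose by 2.86 ± 0.20 and ACSL1, which activates fatty acids, by 2.82 ± 0.17. The largest falls were in GDF15, a stress cytokine (−3.02 ± 0.22, adjusted p = 1.79e-13), TRIML2 (−2.75 ± 0.12), and the transcription factor SOX2 (−2.25 ± 0.16). They were followed by ST8SIA4, a polysialic acid synthase (−2.04 ± 0.13), IER3 (−1.79 ± 0.10), CYP24A1, which breaks down vitamin D (−1.70 ± 0.14), SH3PXD2A (−1.69 ± 0.14) and RND1 (−1.66 ± 0.20). Dex raised 817 genes and lowered 913, 1730 in all, of which 182 rose and 63 fell at least 2-fold. BEST2, ETNK2, ST8SIA4 and RND1 were near background in at least 1 group, and other probes gave smaller values for ANGPTL4 (0.53 and 1.39) and values of 0.66 to 4.65 for TSC22D3.

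A printed count that stands without one adjusted over the list alone was the same in both. Of the 33 tested GR induced genes, 25 rose in siNS cells and 1 fell (25 and 1 adjusted over the list alone, camera, adjusted p = 2.99e-39). All 6 metallothioneins, proteins that bind zinc and copper, rose, among them MT1H (3.16 ± 0.26), MT1G (2.91 ± 0.22), MT1X (2.71 ± 0.23) and MT2A (2.47 ± 0.14, 6 adjusted over the list alone, adjusted p = 6.68e-17). NRF2 targets, which serve antioxidant defence, fell: 11 of 17 (12 adjusted over the list alone, adjusted p = 1.20e-10). HMOX1, which degrades heme, was at −1.45 ± 0.17, the glutathione synthesis genes GCLM and GCLC at −1.29 ± 0.11 and −1.01 ± 0.13, and SRXN1 at −1.21 ± 0.11. Of 24 inflammatory genes 11 fell and 2 rose (12 and 2 adjusted over the list alone, adjusted p = 0.0011), with falls of the prostaglandin synthase PTGS2 (−1.22 ± 0.13) and the chemokines CXCL5 (−1.04 ± 0.14), CCL2 (−0.93 ± 0.15) and CXCL1 (−0.91 ± 0.21). For this list the adjusted p = 0.092 with an estimated correlation. In glucose and lipid metabolism 7 of 21 rose and 2 fell (9 and 3 adjusted over the list alone, adjusted p = 3.02e-04), including the insulin signalling adaptor IRS2 (1.55 ± 0.16).

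Clock genes rose on balance in siNS cells, 4 of 13 against 1 fall (4 and 3 adjusted over the list alone, adjusted p = 0.031, or adjusted p = 0.070 with an estimated correlation). The repressors CIART (1.73 ± 0.15), CRY2 (1.53 ± 0.14) and PER2 (0.92 ± 0.10) rose and the activator NPAS2 fell (−0.59 ± 0.14). Among 33 cell cycle genes 5 fell and 1 rose (6 and 1 adjusted over the list alone, adjusted p = 0.0016, or adjusted p = 0.62 with an estimated correlation). AURKA, TTK and FOXM1, which act in mitosis, fell by 0.52, 0.48 and 0.44, and the cyclin CCND1 rose by 0.62. The interferon list was called higher (adjusted p = 0.021, or adjusted p = 0.82 with an estimated correlation) although IFI6 (1.41 ± 0.33) was its 1 called member of 26 (1 adjusted over the list alone), and the call was lost without siNS dex array 3. Immediate early and RNA decay genes went both ways, 3 higher and 3 lower of 12 (3 and 4 adjusted over the list alone), and the list was not called (adjusted p = 0.79). FOS (2.15) and ZFP36, which destabilises cytokine mRNA (1.89), rose, while IER3 and JUN (−1.01) fell. Ion and water transport was not called at the level of the list (5 higher and 3 lower of 15, 6 and 3 adjusted over the list alone, adjusted p = 0.052) although the kinase SGK1 rose by 2.11 ± 0.13 and the sodium channel subunit SCNN1G by 1.41. The paired fit with a replicate block called it (adjusted p = 0.042).

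**Figure D2:**
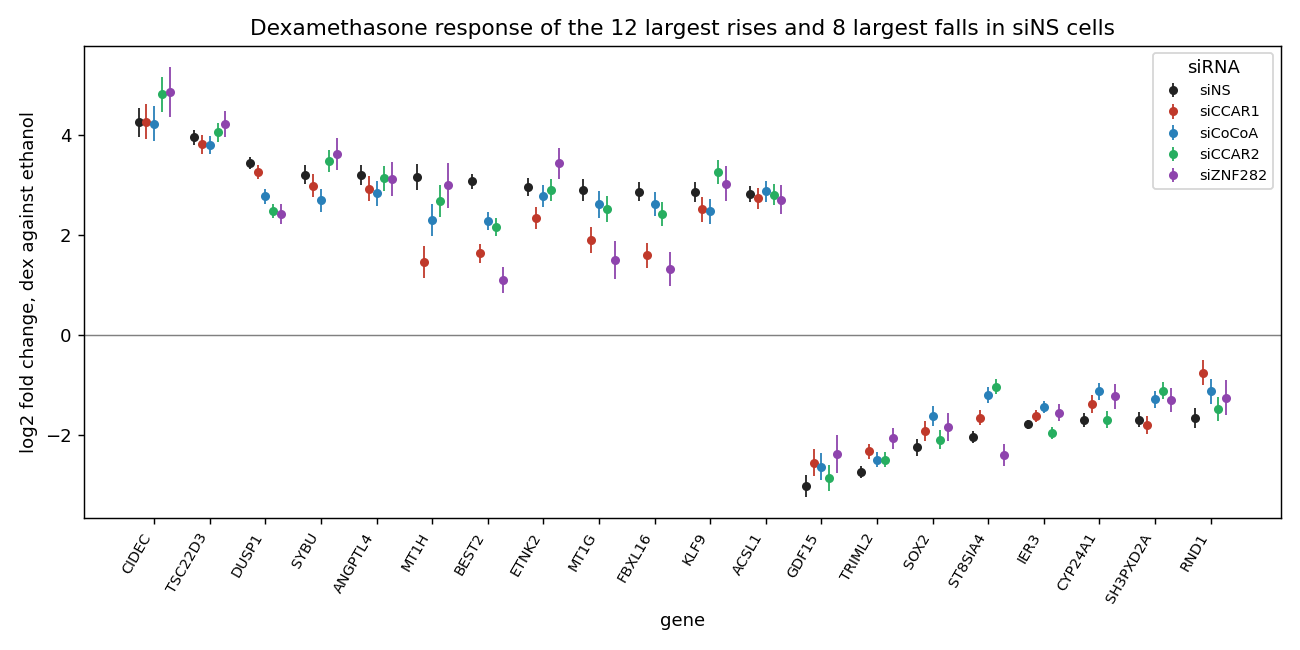
Log2 fold change of dex over ethanol (± SE) for the genes with the 12 largest rises and 8 largest falls in siNS cells, shown for the 5 siRNAs. CIDEC rose by 4.26 and GDF15 fell by 3.02 in siNS cells.

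Whether depleted cells kept a dex response was asked with the same comparison in each. GR induced genes rose in all 4: 22 of 33 with 1 lower in siCCAR1 (24 and 1 adjusted over the list alone, adjusted p = 6.36e-41), 25 with 1 lower in siCoCoA (26 and 1, adjusted p = 6.85e-40), 23 with 1 lower in siCCAR2 (27 and 1, adjusted p = 6.54e-35) and 18 with 0 lower in siZNF282 (23 and 2, adjusted p = 1.43e-23). Metallothioneins rose in 6 of 6 cases in siCCAR1, siCoCoA and siCCAR2 cells and in 4 of 6 in siZNF282 cells (adjusted p = 1.37e-07), the same counts adjusted over the list alone. NRF2 targets fell in 8, 8, 9 and 6 of 17 (10, 12, 12 and 8 adjusted over the list alone). Inflammatory genes fell in siCCAR1 (7 of 24, 9 with 1 higher adjusted over the list alone, adjusted p = 2.72e-04, or adjusted p = 0.058 with an estimated correlation). They also fell in siCCAR2 (8, 12 with 2 higher adjusted over the list alone, adjusted p = 4.92e-05) and siZNF282 cells (5, 7 adjusted over the list alone, adjusted p = 0.0036, or adjusted p = 0.13 with an estimated correlation; not called without siZNF282 ethanol array 2), and were not called as a list in siCoCoA cells.

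The cell cycle list fell with dex in all 4 depletions, as in siNS cells, with medians of −0.27 in siCCAR1 (adjusted p = 7.65e-04), −0.40 in siCoCoA (adjusted p = 6.30e-08), −0.21 in siCCAR2 (adjusted p = 0.030) and −0.34 in siZNF282 (adjusted p = 8.59e-04). Of its 33 genes 1, 6, 0 and 1 were called lower and 1 higher in each (3, 22, 0 and 1 lower and 1 higher adjusted over the list alone). None of the 4 calls held with an estimated correlation (adjusted p = 0.52, 0.28, 0.73 and 0.68). The siCCAR2 call was lost without dex array 3 (−0.10) or 4 (−0.18) or ethanol array 1 (−0.14) or 2 (−0.15), and the siZNF282 call without dex array 3 (−0.05) or ethanol array 2 (−0.23). The clock list was called higher in all 4: in siCCAR1 (4 of 13, with 1 lower adjusted over the list alone, adjusted p = 0.017), siCCAR2 (4, adjusted p = 0.011) and siZNF282 cells (3, 5 adjusted over the list alone, adjusted p = 0.020) it also held with an estimated correlation (adjusted p = 0.044, 0.027 and 0.049). The siZNF282 clock call was lost without dex array 2 or either ethanol array (medians of 0.15 to 0.36, against 0.30). A filter line of 6 ended the siCCAR2 and siZNF282 clock calls (adjusted p = 0.055 in both), and a fit of only the groups compared ended that of siCCAR1 (adjusted p = 0.079). In siCoCoA cells 4 clock genes were higher and 1 lower (adjusted p = 0.033), with a mean of 0.30 but a median of −0.03. That call did not hold with an estimated correlation (adjusted p = 0.082), in the paired fit with a replicate block (adjusted p = 0.057) or without siCoCoA ethanol array 4 (0.03).

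Glucose and lipid metabolism rose in all 4 depletions, with 6, 6, 7 and 6 of 21 genes higher and 3, 1, 1 and 1 lower (9, 7, 8 and 7 higher and 3, 1, 2 and 1 lower adjusted over the list alone). The adjusted p = 1.91e-05, 0.0026, 4.30e-06 and 3.80e-05, and the siCoCoA call did not hold with an estimated correlation (adjusted p = 0.089). The interferon list rose in siCCAR1 (3 of 26, 5 adjusted over the list alone, adjusted p = 4.12e-07) and siCoCoA cells (2, or 1 adjusted over the list alone, adjusted p = 1.11e-05), and neither call held with an estimated correlation (adjusted p = 0.44 and 0.57). Matrix genes rose in siCCAR2 cells (4 of 20 with 1 lower, 7 and 1 adjusted over the list alone, adjusted p = 0.0085). They also rose in siZNF282 (4 with 1 lower, adjusted p = 0.013, or adjusted p = 0.057 with an estimated correlation) and siCoCoA cells (2 with 1 lower, adjusted p = 0.0497, or adjusted p = 0.16 with an estimated correlation). The siZNF282 call was lost without dex array 2 (0.13) or ethanol array 3 (0.16) and the siCoCoA call without any 1 of 6 of its 8 arrays. Ion and water transport rose in siCCAR2 cells (6 of 15 with 1 lower, 6 and 2 adjusted over the list alone, adjusted p = 0.023, or adjusted p = 0.22 with an estimated correlation), and was not called without dex array 4 (0.13) or ethanol array 1 (0.13).

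Dex changed 815 genes in siCCAR1 cells (459 higher, 356 lower), 1053 in siCoCoA (569 and 484), 1031 in siCCAR2 (686 and 345) and 657 in siZNF282 (414 and 243). These counts are not comparable with the 1730 of siNS cells, which had more arrays. Over 15 choices, 4 of the 6 siNS pairs gave 1074 to 1254. For siZNF282 the count fell to 343 without dex array 2, 385 without dex array 3 and 365 without ethanol array 2.

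Depletion of CCAR1 was compared with siNS in each treatment to ask which genes change with it. The largest rises in dex were in interferon-stimulated genes, which act against viruses: IFI27 (3.93 ± 0.60, adjusted p = 1.01e-05), the ubiquitin-like ISG15 (3.92 ± 0.45, adjusted p = 6.28e-08), IFI6 (3.66 ± 0.37), the GTPase MX1 (3.57 ± 0.46), IFIT1 (3.30 ± 0.38) and IFIT2 (3.03 ± 0.44). In ethanol they were at 3.03, 3.73, 3.72, 3.48, 3.44 and 2.48, in that order. The largest falls in dex were in MT1H (−2.32 ± 0.29, adjusted p = 3.21e-07), the protease inhibitor SERPINA3 (−2.31 ± 0.21, adjusted p = 8.85e-10, −1.38 in ethanol), TMX1 (−1.82 ± 0.10, −1.50 in ethanol), the acute phase protein SAA1 (−1.69 ± 0.19, −0.78 in ethanol), FBXL16 (−1.68 ± 0.22) and ENOPH1 (−1.67 ± 0.11, −1.62 in ethanol). In ethanol FBXL16 (−0.40) was not called, and MT1H (−0.62, adjusted p = 0.16) was called lower only in the paired fit with a replicate block (−0.59, adjusted p = 0.0065). SUSD2 fell in dex (−1.54) and ethanol (−1.58 ± 0.19). RND1 (1.23 ± 0.23) and F2RL2 (1.18 ± 0.20), which dex lowers in siNS cells, were higher in depleted dex cells, as was HELZ2 (1.08 ± 0.29); SAA1, RND1 and F2RL2 were near background.

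Among the GR induced genes 10 of 33 were lower and 1 higher in siCCAR1 than siNS cells in dex (13 and 1 adjusted over the list alone, adjusted p = 4.10e-05). The cell cycle inhibitor CDKN1C was at −1.51 ± 0.16, CAVIN2 at −1.12 ± 0.20, TXNIP at −1.07 ± 0.28 and HSD11B2, which inactivates cortisol, at −0.98 ± 0.15. All 6 metallothioneins were lower (6 adjusted over the list alone, adjusted p = 1.10e-07), including MT1F (−1.53 ± 0.23), MT1G (−1.40 ± 0.24) and MT1X (−1.37 ± 0.26). Inflammatory genes were lower, 12 of 24 (adjusted p = 7.46e-05, or adjusted p = 0.069 with an estimated correlation), with PTGS2 at −1.02 ± 0.15, IL32 at −0.97 ± 0.13 and CXCL2 at −0.96 ± 0.18, while the chemokine CCL5 was higher (2.27 ± 0.47). The cell cycle list was lower (9 of 33 with 1 higher, 13 and 1 adjusted over the list alone, adjusted p = 4.10e-05, or adjusted p = 0.44 with an estimated correlation), as for the replication helicase MCM5 (−0.84) and the mitotic cyclin CCNB1 (−0.68). The p53 targets were called higher (7 of 22, with 2 lower, 10 and 2 adjusted over the list alone, adjusted p = 0.040, or adjusted p = 0.44 with an estimated correlation), with SESN1 at 0.89 and ZMAT3 at −0.84. They were not called in the paired fit with a replicate block (adjusted p = 0.054), with the mean of probes (adjusted p = 0.053) or without siCCAR1 dex array 1 or 3 or siNS dex array 2, 4 or 6 (medians of 0.16 to 0.20, against 0.20). NRF2 targets were called higher (2 of 17, with 1 lower, 6 and 1 adjusted over the list alone, adjusted p = 0.019, or adjusted p = 0.072 with an estimated correlation), led by the cystine transporter SLC7A11 (1.49). The interferon list was higher in 22 of 26 (23 adjusted over the list alone, median 2.20, adjusted p = 1.39e-23, or adjusted p = 0.072 with an estimated correlation). In total 1069 genes were higher and 944 lower in dex, and 775 and 690 in ethanol; 1046 were called in the same direction in both.

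Depletion of CoCoA was compared in the same way. The largest rises in dex were IFI27 (5.69 ± 0.60, adjusted p = 4.45e-09), IFIT3 (5.30 ± 0.39), IFIT2 (5.23 ± 0.44), the antiviral protein OASL (5.15 ± 0.39), MX1 (4.96 ± 0.46) and ISG15 (4.94 ± 0.45). In ethanol IFI27, MX1 and ISG15 were at 5.40, 5.28 and 5.19. The largest falls in dex were in ACO1, an aconitase that senses iron (−1.66 ± 0.26, adjusted p = 1.16e-05, −0.88 in ethanol), RFLNB (−1.44 ± 0.23, −0.75), and the proline synthesis enzyme PYCR1 (−1.43 ± 0.18). Next were the tRNA splicing subunit TSEN34 (−1.34 ± 0.10, adjusted p = 1.59e-12), ZMAT3 (−1.29 ± 0.20) and the RNA demethylase ALKBH5 (−1.28 ± 0.11). In ethanol the largest falls were in the creatine kinase CKB (−1.32 ± 0.12), MTX3 (−1.30 ± 0.12) and ZMAT3 (−1.29). Among genes that dex raises or lowers at least 2-fold, RIMKLB (1.65 ± 0.15) and EPSTI1 (1.68 ± 0.26) were higher in depleted dex cells, with IFI6 and HELZ2, while MT1H (−1.15 ± 0.29), SYBU (−0.86 ± 0.21), CXCL5 (−0.86 ± 0.16) and CDKN1C (−0.78 ± 0.16) were lower. The other PYCR1 probe was at −0.07. The ethanol fall of ACO1 was not called without siCoCoA ethanol array 2 (−0.77), nor that of RFLNB without siCoCoA ethanol array 2 or 4 (adjusted p = 0.086 and 0.097).

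In siCoCoA cells all 26 interferon genes were higher in dex (26 adjusted over the list alone, median 3.75, adjusted p = 2.02e-49). Cell cycle genes were lower, 23 of 33 (28 adjusted over the list alone, adjusted p = 4.31e-16, or adjusted p = 0.16 with an estimated correlation). CDC20 was at −0.98 ± 0.17, MCM5 at −0.98 ± 0.21 and the mitotic motor CENPE at −0.97 ± 0.16, and the mitotic kinase CDK1 fell by 1.00 ± 0.14. Inflammatory genes were higher, 9 of 24 with 2 lower (10 and 3 adjusted over the list alone, adjusted p = 0.020, or adjusted p = 0.45 with an estimated correlation), with CXCL10 at 2.46, CCL5 at 1.79, CCL20 at 1.19 and the cytokine IL6 at 1.08; the call was lost without siCoCoA dex array 3. CXCL10 and CCL5 are also induced by interferon. In total 1167 genes were higher and 962 lower in dex, 895 and 745 in ethanol, and 1143 in the same direction in both.

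Depletion of CCAR2 was compared next. In dex the largest rises were in IFI27 (6.03 ± 0.60, adjusted p = 1.72e-09), ISG15 (4.86 ± 0.45), IFITM3 (4.55 ± 0.43) and IFITM1 (4.52 ± 0.53), which block viral entry, IFIT3 (4.31 ± 0.39) and MX1 (4.15 ± 0.46). IFI27, ISG15 and MX1 were at 6.40, 5.54 and 4.95 in ethanol. The largest falls in dex were in UBL3 (−1.58 ± 0.16, adjusted p = 1.97e-09, −1.44 in ethanol), the mitochondrial fission factor MIEF1 (−1.56 ± 0.12, −1.21) and KITLG, the ligand of the KIT receptor (−1.53 ± 0.25, adjusted p = 1.86e-05), which was −0.53 and not called in ethanol. Close to these were the transcription factor SPDEF (−1.45 ± 0.18, −0.90), ENC1 (−1.45 ± 0.15, −1.19) and the RNA-binding protein CIRBP (−1.40 ± 0.12, adjusted p = 7.42e-11, −1.25). In ethanol AGPAT2, a lipid synthesis enzyme (−1.51 ± 0.11, adjusted p = 1.60e-12), the glucose-6-phosphate transporter SLC37A4 (−1.51 ± 0.11) and CSGALNACT1 (−1.48 ± 0.13) fell most. Among genes changed at least 2-fold by dex, the GTPase RRAD (1.30 ± 0.18) and RIMKLB (1.41) were higher in depleted dex cells, with IFI6 and HELZ2, while KITLG, RHOBTB3 (−1.10 ± 0.13), the hyaluronan-binding CEMIP (−1.07 ± 0.20) and CIDECP1 (−1.03 ± 0.16) were lower. In siNS cells dex raised KITLG (1.62), CIDECP1 (2.24) and RHOBTB3 and lowered CEMIP (−1.26). Another RIMKLB probe was at 0.55.

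In siCCAR2 cells in dex all 26 interferon genes were higher (26 adjusted over the list alone, median 3.28, adjusted p = 2.63e-41). Matrix and mesenchymal genes were higher, 7 of 20 (7, with 1 lower, adjusted over the list alone, adjusted p = 0.0021), among them the basement membrane collagens COL4A1 (1.76 ± 0.15) and COL4A2 (1.18 ± 0.15), CCN1 (1.10 ± 0.11) and TGFBI (0.95 ± 0.12). Inflammatory genes were higher, 10 of 24 (adjusted p = 0.0073, or adjusted p = 0.23 with an estimated correlation), with CCL5 at 2.94, CCL20 at 1.36, CXCL10 at 1.23 and NFKB2 at 0.92, and the call was lost without siCCAR2 dex array 2. Immediate early genes were higher, 4 of 12 (adjusted p = 0.049, or adjusted p = 0.088 with an estimated correlation), with the phosphatase DUSP5 at 1.58 and the stress factor ATF3 at 0.95; leaving out any 1 of 6 arrays ended this call. In total 1115 genes were higher and 888 lower in dex, 768 and 950 in ethanol, and 1077 in the same direction in both.

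Depletion of ZNF282 was compared with 2 arrays per group. In dex the rises were led by IFITM1 (7.47 ± 0.67, adjusted p = 7.05e-11), IFI27 (7.41 ± 0.76), IFIT2 (7.19 ± 0.55), OASL (6.70 ± 0.49), LAMP3 (6.70 ± 0.58) and IFIT3 (6.70 ± 0.50), and in ethanol by IFI27 (8.22), IFIT2 (7.75) and IFITM1 (7.73). The falls in dex were led by ACO1 (−2.83 ± 0.33, adjusted p = 2.25e-08, −2.59 in ethanol), PDK3, a kinase that inhibits pyruvate dehydrogenase (−2.29 ± 0.31, −1.86), FBXL16 (−2.16 ± 0.28), HMGN5 (−2.03 ± 0.24) and LRRC49 (−1.95 ± 0.18, −1.73 in ethanol). ZNG1C fell by 2.00 ± 0.30 (−1.73 in ethanol). FBXL16 (−0.61) and HMGN5 (−0.52) were not called in ethanol, where RFLNB (−1.89 ± 0.29) was lower and TELO2 fell by 2.00 ± 0.57 (adjusted p = 0.0064). Among genes changed at least 2-fold by dex, FZD4, a Wnt receptor (2.31 ± 0.25), and EPSTI1 (3.04) were higher in depleted dex cells, with IFI6 and HELZ2, and FBXL16, BEST2 (−1.90 ± 0.21), PHACTR3 (−1.49 ± 0.20) and TUBA3E (−1.40 ± 0.16) were lower. LAMP3, HMGN5, TELO2, BEST2, PHACTR3 and TUBA3E were near background, and the other PDK3 probe was at −0.98. Without siZNF282 ethanol array 2, TELO2 and the ethanol fall of ZNG1C (−0.77) were not called, TELO2 was not called with arrayWeights (−2.01, adjusted p = 0.058), and without siNS ethanol array 4 FBXL16 was called in ethanol (−0.72).

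In siZNF282 cells in dex all 26 interferon genes were higher (26 adjusted over the list alone, median 5.15, adjusted p = 1.08e-38). Inflammatory genes were higher in 18 of 24 (18, with 1 lower, adjusted over the list alone, adjusted p = 3.77e-09), with CXCL10 at 5.36 ± 0.50, CCL5 at 5.20 ± 0.59, IL6 at 2.90 ± 0.28 and CCL20 at 2.36 ± 0.27. Matrix genes were higher in 11 of 20 and lower in 1 (adjusted p = 9.20e-05), with COL4A1 at 2.73 ± 0.18, the integrin ITGA5 at 1.96 ± 0.25, COL5A1 at 1.60 ± 0.24 and LAMB3 at 1.48 ± 0.26. Immediate early genes were higher in 8 of 12 (10 adjusted over the list alone, adjusted p = 1.84e-04), with DUSP5 at 1.74, ATF3 at 1.45, JUN at 1.23 and JUNB at 1.10. Cell cycle genes were lower in 12 of 33 (13 adjusted over the list alone, adjusted p = 4.09e-05, or adjusted p = 0.31 with an estimated correlation), with UBE2C at −1.21 and CDC20 at −1.06. Wnt targets were higher, 6 of 15 with 1 lower (7 and 1 adjusted over the list alone, adjusted p = 0.015, or adjusted p = 0.076 with an estimated correlation), as for the receptor FZD7 (1.33) and the feedback inhibitor NKD2 (0.99). NRF2 targets were lower in 6 of 17 (adjusted p = 0.046, or adjusted p = 0.12 with an estimated correlation), with HMOX1 at −1.27, and were not called without siZNF282 dex array 3 or siNS dex array 2 or 5. Ribosomal protein genes were lower in 9 of 23 (10 adjusted over the list alone, adjusted p = 0.0050, or adjusted p = 0.068 with an estimated correlation), with RPL7 at −0.87 and RPL5 at −0.85.

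In total 1642 genes were higher and 1589 lower in siZNF282 than siNS cells in dex, 1537 and 1818 in ethanol, and 2181 in the same direction in both. With 2 arrays per group these counts depend on single arrays: 3231 in dex became 1826 without dex array 2, and 3355 in ethanol became 1521 without ethanol array 2.

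The interferon list also varied among the siNS dex arrays, with list means of 5.60 to 7.28, and each target had 1 siRNA label.

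**Figure D3:**
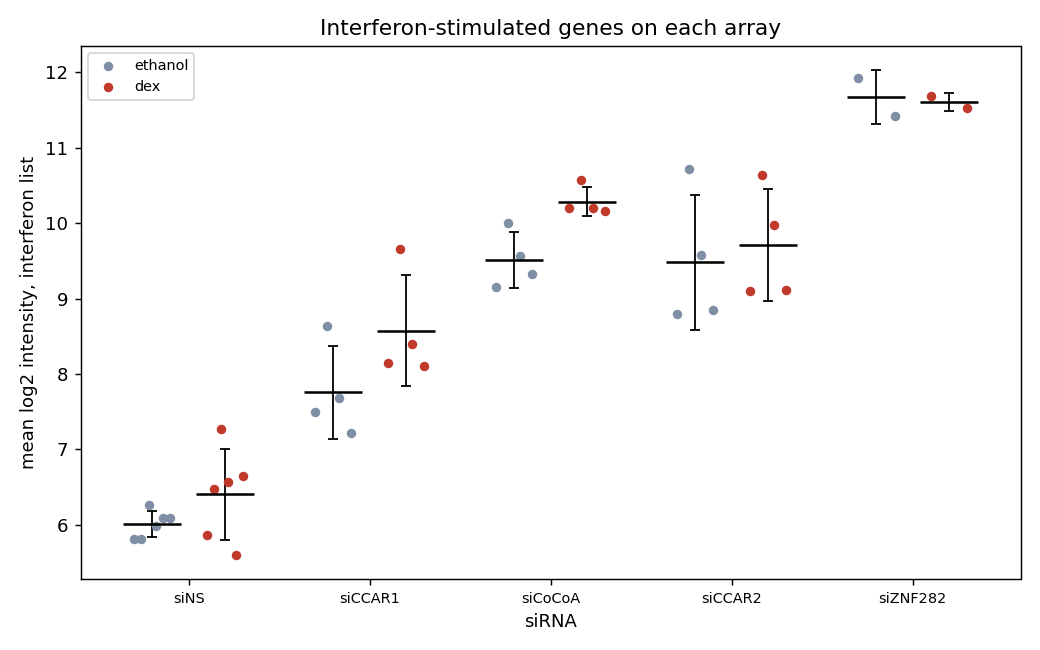
Mean log2 intensity of the 26 interferon list genes on each array, for the 10 groups; points are arrays, lines are group means and bars are the SD. Group means in ethanol were 6.01 in siNS, 7.75 in siCCAR1, 9.51 in siCoCoA, 9.48 in siCCAR2 and 11.7 in siZNF282 cells.

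How far the 4 depletions changed the same genes was asked in dex. In all 4, 174 genes were called in the same direction, 133 higher and 41 lower, and 22 of the 26 interferon list genes were among the 133. Those with the clearest calls were IFI6 (3.66, 4.19, 3.86 and 5.05 in siCCAR1, siCoCoA, siCCAR2 and siZNF282), the double-stranded RNA sensor EIF2AK2 (1.43, 2.11, 1.73 and 2.10), and PARP9 (2.40, 3.37, 2.78 and 3.71). ISG15 (3.92, 4.94, 4.86 and 5.88), IFIT1 (3.30, 4.59, 3.78 and 5.32) and the helicase DDX60 (2.57, 3.67, 3.27 and 3.58) came next. They were followed by LIN28B, which blocks let-7 processing (1.28, 1.15, 1.17 and 1.36), and SP110 (1.64, 2.72, 1.93 and 3.41).

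Over the 6 pairs of coregulators, CoCoA and ZNF282 shared most calls in the same direction (1057, with 102 in opposite directions), then CCAR2 and ZNF282 (906 and 119) and CCAR1 and ZNF282 (648 and 233). Fewer were shared by CoCoA and CCAR2 (569 and 124), CCAR1 and CoCoA (541 and 130) and CCAR1 and CCAR2 (458 and 175). Independent calls would share 325, 306, 307, 203, 203 and 191. All comparisons used the same siNS arrays. Simulated unchanged groups with those arrays shared at most 1 call. With means of 0.3 to 1.66 calls, they cannot show how far shared arrays add to overlaps of long lists. With separate sets of 3 siNS dex arrays per member of a pair the medians were 699.5, 574.5, 401, 326, 294.5 and 227. Across genes, which are not independent replicates, the median r of the changes with those sets was 0.60, 0.52, 0.27, 0.43, 0.32 and 0.24, in the same order. Effects of siNS itself would enter every overlap and r above, and separate arrays do not remove them.

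**Figure D4:**
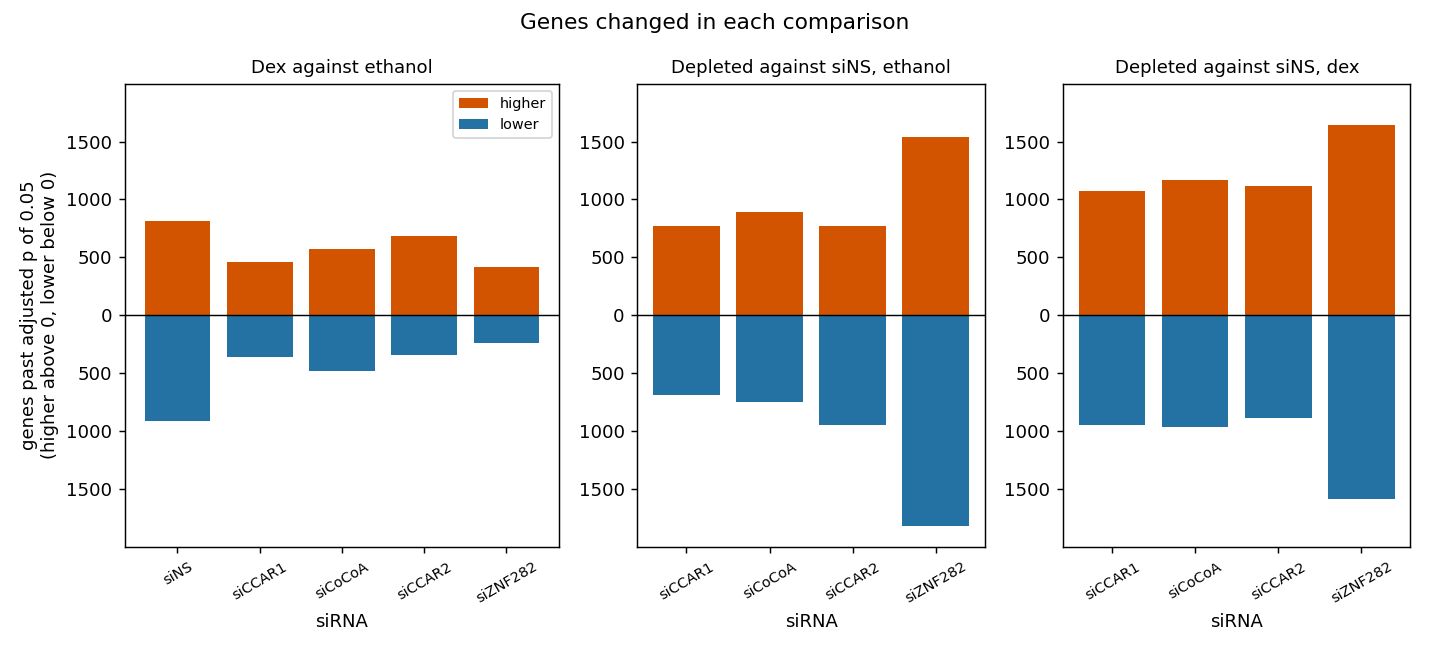
Number of genes called higher (bars above 0) and lower (bars below 0) in the 5 comparisons of dex with ethanol and the 8 of depleted with siNS cells. In dex the depletions gave 1069 higher and 944 lower genes for siCCAR1 and 1642 and 1589 for siZNF282.

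The next question was how many dex-regulated genes each depletion altered in dex cells. Of the 1730 genes that dex changed in siNS cells, siCCAR1 altered 515 (29.8%, against 16.9% of other genes), siCoCoA 505 (29.2% against 18.3%), siCCAR2 492 (28.4% against 17.0%) and siZNF282 658 (38.0% against 29.0%). Genes raised by dex were lower in depleted cells in 189, 81, 136 and 130 cases and higher in 59, 119, 111 and 171, in that order. Genes lowered by dex were higher in 194, 213, 175 and 230 cases and lower in 73, 92, 70 and 127. MT1H, SERPINA3 and FBXL16 are examples of the first kind in siCCAR1 cells, and RND1 and F2RL2 of the third. Of the 1730 genes, 506 were altered by no depletion, 589 by 1, 385 by 2, 189 by 3 and 61 by all 4. Both comparisons use the siNS dex arrays, which favours changes against the dex response. With separate sets of 3 siNS dex arrays for the 2 comparisons the median numbers altered were 285, 297.5, 291 and 419. Simulated unchanged groups gave at most 6, 6, 36 and 8. With means of 0.3 to 1.66 depletion calls, they cannot show how far shared arrays add to this. In the paired fit with a replicate block siCoCoA altered 771, and siZNF282 altered 405 without its dex array 2.

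The last question was whether depletion changed the dex response itself, which is the difference of differences. In siCCAR1 cells 10 responses were lower and 1 higher. CDKN1C, a cell cycle inhibitor, rose by 2.46 in siNS and 0.98 in depleted cells (difference −1.48 ± 0.22, adjusted p = 8.35e-04), and BEST2 by 3.08 and 1.63 (−1.45 ± 0.24, adjusted p = 0.0015). ALOX5AP, which serves leukotriene synthesis, rose by 2.33 and 0.85 (−1.48 ± 0.31, adjusted p = 0.033) and PHACTR3 by 1.98 and 0.68 (−1.30 ± 0.22, adjusted p = 0.0028). PAQR9 changed by −0.58 and 0.55 (1.13 ± 0.22, adjusted p = 0.018). In siCoCoA cells 1 gene passed: EMP1, a membrane protein, rose by 2.49 in siNS and 1.19 in depleted cells (−1.30 ± 0.24, adjusted p = 0.049, unadjusted p under 0.05 for 523 genes), where its ethanol level was 8.19 against 6.72 in siNS. The GR induced list responded less in siCCAR1 (2 of 33 genes lower, 3 adjusted over the list alone, adjusted p = 0.011), siCoCoA (0, or 1 adjusted over the list alone, adjusted p = 0.037) and siZNF282 cells (1, or 5 adjusted over the list alone, adjusted p = 0.0013). So did the metallothioneins, with 0, 0 and 1 of 6 genes lower, 2, 1 and 2 adjusted over the list alone (adjusted p = 8.13e-05, 0.0064 and 7.44e-04). None of these calls held with an estimated correlation (adjusted p = 0.30, 0.55 and 0.14 for GR induced genes and 0.13, 0.55 and 0.14 for metallothioneins, with an estimated correlation). The siCCAR1 call of GR induced genes, with a median of −0.06, was also lost without siCCAR1 dex array 1 or ethanol array 3 (−0.03 in both) or siNS dex array 3 (−0.05). The siCoCoA call was lost in 9 of 20 fits that left out 1 array (adjusted p = 0.020 to 0.25 over the 20) and with no filter (adjusted p = 0.12), and that of metallothioneins in siZNF282 cells with no filter (adjusted p = 0.063). The ethanol levels differed too: at the preset correlation GR induced genes were higher than in siNS in siCoCoA and siZNF282 cells and lower in siCCAR1 cells. Metallothioneins in ethanol were higher in siZNF282 and lower in siCCAR1 cells. The interferon list responded more in siCCAR1 and siCoCoA cells and less in siZNF282 cells (adjusted p = 0.0022, 0.015 and 0.0047, or adjusted p = 0.77, 0.73 and 0.92 with an estimated correlation), with 0 genes called. These calls rested on single arrays. In siCCAR1 cells the median of 0.55 was 0.17 without siCCAR1 dex array 2 (adjusted p = 0.82), and the call was also lost without siCCAR1 ethanol array 4 (0.35) or siNS dex array 5 (0.43). In siCoCoA cells the call was lost without siCoCoA dex array 2, ethanol array 1 or 4, siNS dex array 1 or 5 or ethanol array 3 (0.31 to 0.38, against 0.41). In siZNF282 cells it was lost without siNS dex array 3, siZNF282 dex array 3 or ethanol array 2 (−0.24, −0.45 and −0.21, against −0.41). With arrayWeights the values were 0.12 (adjusted p = 0.93) for siCCAR1 and 0.31 (adjusted p = 0.65) for siCoCoA. In siCoCoA cells inflammatory genes responded upward and cell cycle genes downward (adjusted p = 0.012 and 0.0064, or adjusted p = 0.55 and 0.73 with an estimated correlation), with 0 genes called and 0 and 1 adjusted over the list alone. The first was lost without siCoCoA dex array 3, and the second, with a median of −0.15, without siCoCoA dex array 3 (−0.06) or 4 (−0.05), ethanol array 2 (−0.05) or siNS dex array 2 (−0.09). The counts of 0 are from limma, which gave an unadjusted p under 0.05 for 385 genes in siCCAR1, 523 in siCoCoA and 934 in siZNF282 cells.

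In siCCAR2 cells 7 responses were higher and 2 lower. TUBA3E, a tubulin, rose by 1.37 in siNS and 2.64 in depleted cells (1.26 ± 0.18, adjusted p = 5.12e-04), and OTOF by 0.17 and 1.31 (1.14 ± 0.22, adjusted p = 0.018). PHYHIPL changed by −0.94 and 0.16 (1.09 ± 0.23, adjusted p = 0.031), and ST8SIA4 by −2.04 and −1.03 (1.01 ± 0.20, adjusted p = 0.023). ARL14 changed by −0.15 and −1.51 (−1.37 ± 0.23, adjusted p = 0.0034), and DUSP1 by 3.44 and 2.48 (−0.96 ± 0.18, adjusted p = 0.018). In ethanol DUSP1 was 10.2 and ARL14 6.00, against 8.80 and 4.76 in siNS cells. This left ARL14 little room to fall in siNS cells. In siZNF282 cells 9 were higher and 17 lower. MT2A rose by 2.47 in siNS cells and changed by 0.46 in depleted cells (−2.01 ± 0.29, adjusted p = 3.67e-04), and BEST2 by 3.08 and 1.10 (−1.98 ± 0.30, adjusted p = 5.42e-04). GFER, a mitochondrial sulfhydryl oxidase, changed by 0.18 and −1.43 (−1.61 ± 0.33, adjusted p = 0.020) and HMGN5 by 0.54 and −0.97 (−1.51 ± 0.35, adjusted p = 0.044). OTOF changed by 0.17 and 1.71 (1.54 ± 0.27, adjusted p = 0.0049), and KBTBD8 by −0.03 and 1.35 (1.37 ± 0.32, adjusted p = 0.049). SIPA1L2 changed by −0.75 and 0.54 (1.29 ± 0.26, adjusted p = 0.017) and MIPEP by −0.03 and 1.24 (1.27 ± 0.28, adjusted p = 0.036). The MT2A ethanol level in depleted cells, 13.7, lay near the array maximum of 14.32, which limits a further rise.

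The counts of 11, 1, 9 and 26 differences depended on the fit. With the replicate block they were 19, 1, 21 and 65. For siCCAR1 the count was 5 without ethanol array 1 and 6 without ethanol array 4 or dex array 2. For siCCAR2 it was 3 without dex array 2, 4 without ethanol array 2 and 17 without ethanol array 1. For siZNF282 it was 8 without dex array 2, 17 without siNS ethanol array 2 or 6, and 261 without ethanol array 3.

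Single genes differed in how firmly they were called. EMP1 lost its call in 14 of 20 fits that left out 1 array, over which its difference ranged from −1.42 to −1.20, ALOX5AP in 12 of 20 (−1.63 to −1.32), PHYHIPL in 8 of 20 (0.90 to 1.23), KBTBD8 in 13 of 16 (1.08 to 1.66) and HMGN5 in 9 of 16 (−1.87 to −1.16). MIPEP lost it in 8 of 16 and fell to 0.62 without siZNF282 ethanol array 2, and was 1.92 without ethanol array 3. PAQR9 lost it without siCCAR1 dex array 2 (0.98) or ethanol array 1 (1.06) or 4 (1.07), DUSP1 without siCCAR2 ethanol array 2 (−0.82), and ST8SIA4 without siCCAR2 dex array 2 (0.99) or 4 (0.95), ethanol array 3 (0.95) or siNS ethanol array 4 (0.97). OTOF lost it without siCCAR2 dex array 2 (0.93) or ethanol array 2 (1.03) and without siZNF282 dex array 2 (1.14). SIPA1L2 lost it without siZNF282 dex array 3 (1.02) or ethanol array 2 (0.97), and GFER without siZNF282 dex array 2 (−1.64) or 3 (−1.58) or ethanol array 2 (−0.98). PHACTR3 lost its call with the mean of its probes (−0.64). In some fits that left out 1 array, the dex responses of depleted cells were themselves not called for ALOX5AP, PAQR9 and PHACTR3 in siCCAR1 and for BEST2, GFER, HMGN5, KBTBD8, MIPEP and SIPA1L2 in siZNF282 cells. CDKN1C, BEST2, TUBA3E, ARL14 and MT2A kept theirs in every fit that left out 1 array. Except for PAQR9, EMP1, DUSP1, SIPA1L2, MIPEP and MT2A, the genes named for a difference were near background in some group.

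**Figure D5:**
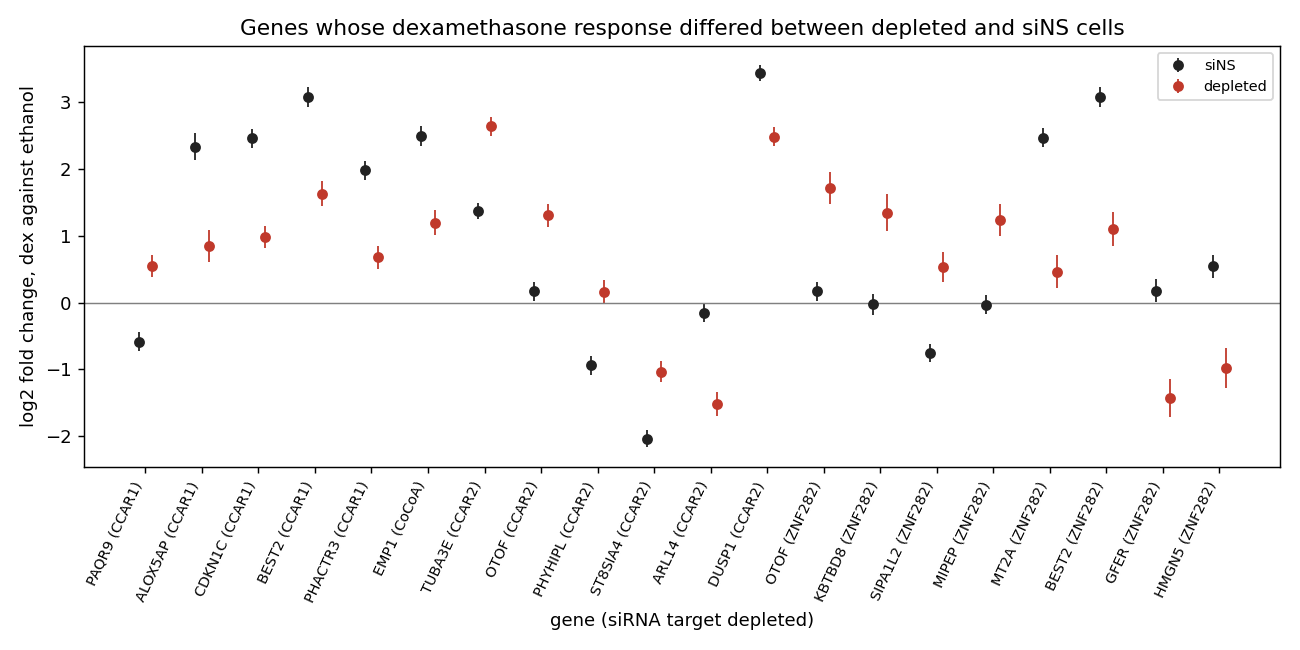
Log2 fold change of dex over ethanol (± SE) in siNS cells and in the depleted cells, for genes whose dex response differed between them. MT2A rose by 2.47 in siNS cells and BEST2 by 3.08, against 0.46 and 1.10 in siZNF282 cells.

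The overall size of the dex response was compared over genes that the other 3 depletions had marked as dex-regulated, so that neither the siNS arrays nor those of the depletion compared chose them. It was smaller in siCCAR1 cells, at 85.8% of siNS over 622 genes (median difference −0.13, fry adjusted p = 0.0107), where 69.5% of the genes responded less. In siCoCoA cells it was smaller as well, at 90.3% over 581 genes (−0.10, adjusted p = 0.0465), with 65.1% responding less, and in siZNF282 cells at 90.2% over 599 genes (−0.11, adjusted p = 0.0465), with 60.9%. In siCCAR2 cells it was 99.9% over 578 genes (−0.02, adjusted p = 0.522), with 53.8%. The fry test asks whether the set moved one way on balance and does not compare it with other genes. The siCoCoA call was lost in 12 of 20 fits that left out 1 array (−0.12 to −0.0684) and the siZNF282 call in 9 of 16 (−0.13 to −0.0828).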

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

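The tests of low values on the siNS arrays, of siCCAR2 RNA in siCoCoA arrays, of high CCAR2 on siNS arrays, of array number and of other splits were fixed beforehand; the tests of normalization, of a response to transfected RNA, of loss of each target, of CoCoA loss for CCAR2, of smaller responses in siCCAR1 cells and of the siCCAR1 count alone were chosen only after the results were seen.

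Of 64 combinations of 8 measures and 8 groups of at least 4 arrays, 3 had an array far from the others. This is close to the share of about 1 in 20 that chance gives. CCAR1 on siNS dex array 4 was 4.60, with the others between 5.66 and 6.10. CALCOCO1 on siCoCoA ethanol array 1 was 5.00, with the others between 4.68 and 4.73. The mean of the interferon list on siCoCoA dex array 2 was 10.6, with the others between 10.16 and 10.20.

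In 20 cases the dex response of a named gene tested as different from siNS (difference in brackets). In siCCAR1 cells these were PAQR9 (1.13), ALOX5AP (−1.48), CDKN1C (−1.48), BEST2 (−1.45) and PHACTR3 (−1.30), and in siCoCoA cells EMP1 (−1.30). In siCCAR2 cells they were TUBA3E (1.26), OTOF (1.14), PHYHIPL (1.09), ST8SIA4 (1.01), ARL14 (−1.37) and DUSP1 (−0.96). In siZNF282 cells they were OTOF (1.54), KBTBD8 (1.37), SIPA1L2 (1.29), MIPEP (1.27), MT2A (−2.01), BEST2 (−1.98), GFER (−1.61) and HMGN5 (−1.51). BEST2 and OTOF count for each depletion.

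Interferon-stimulated genes were higher than in siNS cells in all 4 depletions, with list medians of 1.66 to 5.59. Low values on a few siNS arrays are argued against, as all 28 depleted arrays lay above the highest siNS array of the same treatment. The median of all genes moved by at most 0.0758, but the deposited values had already been normalized between arrays. That normalization holds array medians alike, so this test cannot decide whether normalization contributed. A response to transfected RNA whatever its target may contribute: the list also varied among the 6 pairs of siNS arrays, with an SD of 0.352, larger than in 100% of 10000 random lists of like expression (95th percentile 0.0691). That test is weak, because co-regulated lists vary more than random ones and the metallothioneins came next with 0.248. Loss of each target stays open, since 1 siRNA label per target cannot part it from effects of the siRNA itself.

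CCAR2 transcript was lower in siCoCoA cells, at 51.5% and 46.7% of the siNS level. siCCAR2 RNA in those arrays is argued against: the 55 other genes at least 2-fold lower in siCCAR2 cells had a median of −0.0117 in siCoCoA cells in dex (bootstrap bound −0.121), where a mixture giving that CCAR2 level would give −0.687. High CCAR2 on the siNS arrays is argued against too, as all 8 siCoCoA arrays lay below every siCCAR1 and siZNF282 array of the same treatment, and against the mean of those groups the difference was −0.81 in ethanol and −0.96 in dex. Whether the loss of CoCoA or another target of the siRNA lowered CCAR2 cannot be told apart, since there was 1 siRNA label against CALCOCO1, and either could be involved.

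With all arrays, fewer genes were called for dex in depleted than in siNS cells. With only arrays numbered 2 and 3 (2 per group), siNS cells had 430 calls, siCCAR1 304 and siCoCoA 364. Both siCCAR2 (583) and siZNF282 (516) had more. In the main fit array number alone is argued against for siCCAR1 (815), as 15 overlapping choices of 4 siNS pairs gave 1074 or more. With arrayWeights siCCAR1 had 1445 and all siNS arrays 2107, but the choices were not refitted. For the 3 depleted groups of 4 array number stays open: the highest, 1053, lay below 1074 by less than the SD of choices, 52.8. Smaller responses in siCCAR1 cells may contribute, with a median difference of −0.126 over the genes that the other 3 depletions marked as dex-regulated.

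Other splits of the same arrays were refitted, 35 or 100 per comparison, and 1 split, the real one, gave the largest count in most. Over all splits chance is argued against for the dex responses of siNS (1730 genes, highest other 769), siCCAR1 (815 and 0), siCoCoA (1053 and 35) and siCCAR2 (1031 and 226). Splits that part all pairs, as the real one does, numbered 9, 8, 8 and 8 with the real one included. Among these the highest others were 489, 0, 0 and 3. Over all splits it is also argued against for depletion in ethanol (siCCAR1 1465 and 243, siCoCoA 1640 and 390, siCCAR2 1718 and 358) and in dex (2013 and 603, 2129 and 972, 2003 and 568). Pair-parting splits numbered 7, 8 and 6 in ethanol (highest others 0, 178 and 329) and 5, 7 and 7 in dex (13, 115 and 118). So few pair-parting splits cannot give a share under 0.05, and on their own they cannot exclude chance. The other splits leave some pairs together, and so also compare arrays of different numbers. For differences in dex response the real count and the highest other were 11 and 1 for siCCAR1 and 9 and 1 for siCCAR2. The other splits put depleted and siNS pairs in one group, so the depletion effects widen the spread and lower their counts. They therefore cannot exclude chance for these differences. For siCoCoA the real count and the highest other were both 1, with 3 of 100 splits giving as many; a count of 0 or 1 decides little, and its 1 gene, EMP1, lost its call in 14 of 20 fits that left out 1 array. For the size of the response 3 of 100 splits, the real one included, were as large for siCCAR1 (−0.126, highest other −0.129) and only the real one for siCoCoA (−0.0964 and −0.0860). These shares are under 0.05 but are not adjusted over the split tests, so they argue against chance without excluding it. The margin was narrow: another split passed the siCCAR1 value, and the siCoCoA value was −0.0684 without its dex array 2 and lost its call in 12 of 20 fits that left out 1 array. For siCCAR2 the splits do not argue against chance (−0.0212 and −0.0816, with 56 of 100 splits as large). Groups of 2 siZNF282 arrays were not split.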

How the results depend on the processing

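The filter line of 6, arrays centred on their median, only arrays numbered 2 and 3, and leaving out arrays numbered 1 or both siNS arrays numbered 5 were tests chosen only after results were seen; the others were fixed beforehand. No gene, knockdown or size that was called changed sign and no list that stayed called changed its direction in camera. The median of the clock list in the siCoCoA dex response, −0.03, changed sign in some fits (0.07 without siCoCoA ethanol array 3), while camera gave a rise. The siCCAR2 size, which was not called (−0.0212), was 0.00575 without siCCAR2 dex array 1. Apart from leaving out single arrays, 221 of 270 counts, 76 of 80 knockdowns, 32 of 40 response sizes, 998 list calls (113 lost) and 2640 named gene values (96 lost, 5 gained) stayed on their side of the threshold or within 1.5 times; all counts, knockdowns, sizes and lists did so with arrays centred on their median. The cause of the changes below was not tested, except where fewer arrays per group or a different number of genes give it. Fits that need signals paired with samples were not run, as given above.

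Further list calls lost were, with no filter, the clock in the siNS and siCoCoA dex responses (adjusted p = 0.065 and 0.062), matrix genes in that of siCoCoA (adjusted p = 0.15), ion and water transport for siZNF282 in ethanol (adjusted p = 0.068) and, among differences, GR induced genes for siCoCoA (adjusted p = 0.12) and metallothioneins for siZNF282 (adjusted p = 0.063). With the mean of probes they were p53 targets for siCCAR1 in dex (adjusted p = 0.053) and Wnt targets for siZNF282 in ethanol (adjusted p = 0.074). With only the groups compared they were the clock in the siNS and siCCAR1 dex responses (adjusted p = 0.053 and 0.079). With arrayWeights they were the cell cycle in the siCCAR2 dex response (adjusted p = 0.36) and the interferon differences for siCCAR1 (adjusted p = 0.93) and siCoCoA (adjusted p = 0.65). A filter line of 6 lost 12: the clock (siNS, siCoCoA, siCCAR2, siZNF282), matrix (siCoCoA), ion transport and cell cycle (siCCAR2) for dex responses; p53 for siCCAR2 in ethanol and siCCAR1 in dex (adjusted p = 0.11); immediate early for siCCAR2 (adjusted p = 0.10) and NRF2 for siZNF282 in dex (adjusted p = 0.070); and GR induced for the siCCAR1 difference (adjusted p = 0.079). Only arrays numbered 2 and 3 lost 16: the clock and matrix (siCoCoA) and ion transport (siCCAR2) for dex responses; cell cycle and p53 for siCCAR2, and ER stress and ribosomal genes for siZNF282, in ethanol; p53 and NRF2 for siCCAR1 and immediate early for siCCAR2 in dex; and for differences GR induced and interferon (siCCAR1 and siCoCoA), metallothioneins and cell cycle (siCoCoA). Leaving out arrays numbered 1 lost 5: matrix (siCoCoA), ion transport and cell cycle (siCCAR2) for dex responses, p53 for siCCAR2 in ethanol and the siCoCoA interferon difference. Leaving out both siNS arrays numbered 5 lost 5: p53 for siCCAR2 in ethanol, NRF2 for siZNF282 in dex, the interferon differences for siCCAR1 and siCoCoA and the GR induced difference for siCoCoA (adjusted p = 0.069).

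Among the named differences, no filter lost ALOX5AP, EMP1, HMGN5, KBTBD8 and MIPEP. Only the groups compared lost these 5 and PAQR9, DUSP1, PHYHIPL, GFER, SIPA1L2 and both of OTOF, and arrayWeights lost DUSP1, PHYHIPL, ST8SIA4, GFER, HMGN5, KBTBD8, MIPEP, SIPA1L2 and both of OTOF.

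No filter (more genes): differences in dex response 0 for siCoCoA and 17 for siZNF282. Mean of probes: size −0.0925 for siCoCoA (adjusted p = 0.061) and −0.11 for siZNF282 (adjusted p = 0.057). Only the groups compared (fewer arrays): dex calls 600 in siCCAR2 and 75 in siZNF282; differences 6, 0, 3 and 2 for siCCAR1, siCoCoA, siCCAR2 and siZNF282; CALCOCO1 in ethanol −0.44 (adjusted p = 0.064); size −0.10 for siCoCoA and −0.11 for siZNF282 (both adjusted p = 0.072). Replicate block: differences 19, 21 and 65 for siCCAR1, siCCAR2 and siZNF282, and 771 altered genes for siCoCoA; among named genes it added MT1H (−0.59) in siCCAR1 and SYBU (−0.40) in siCoCoA cells, both in ethanol, and it changed no other named gene; among lists it added, for the siNS dex response, ion and water transport, matrix genes and hypoxia (each adjusted p = 0.042), for the siCCAR2 dex response hypoxia (adjusted p = 0.017) and for siCCAR2 in dex metallothioneins (adjusted p = 0.034), and it lost the clock for the siCoCoA dex response (adjusted p = 0.057) and p53 targets for siCCAR1 in dex (adjusted p = 0.054). arrayWeights: dex calls 1445 in siCCAR1 and 364 in siZNF282; depletion in ethanol 2492 and 2050; differences 3 for siCCAR2 and 2 for siZNF282. Estimated correlation: 41 of 101 list calls. Filter line of 6 (fewer genes): 9 differences for siZNF282.

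Only arrays numbered 2 and 3 (fewer arrays): dex calls 430, 304, 364, 583 and 516 in siNS, siCCAR1, siCoCoA, siCCAR2 and siZNF282 (within 1.5 times for siZNF282); depletion in ethanol 186, 258, 631 and 1956 and in dex 309, 387, 497 and 1991 for siCCAR1, siCoCoA, siCCAR2 and siZNF282; differences 0, 0, 2 and 1; altered genes 53, 38, 58 and 131. Shared calls were 68 (CCAR1 and CoCoA), 68 (CCAR1 and CCAR2), 118 (CCAR1 and ZNF282), 122 (CoCoA and CCAR2), 244 (CoCoA and ZNF282) and 259 (CCAR2 and ZNF282); in ethanol CCAR1 was −0.72 (adjusted p = 0.19) and CALCOCO1 −0.75 (adjusted p = 0.053); size −0.15 (adjusted p = 0.16), −0.11 (adjusted p = 0.21) and −0.11 (adjusted p = 0.18) for siCCAR1, siCoCoA and siZNF282. Without arrays numbered 1: differences 7 for siCCAR1 and 0 for siCoCoA; CALCOCO1 in ethanol −0.47 (adjusted p = 0.055); size −0.10 for siCoCoA (adjusted p = 0.054). Without both siNS arrays numbered 5: differences 0 for siCoCoA and 17 for siZNF282.

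Leaving out 1 array gave 1826 (siZNF282 dex array 2) to 3173 genes for siZNF282 depletion in dex and 1521 (ethanol array 2) to 3273 in ethanol; 343 (dex array 2) to 863 dex calls in siZNF282; 405 (dex array 2) to 650 altered genes for siZNF282; differences of 5 to 11 for siCCAR1, 0 to 2 for siCoCoA (2 without siNS dex array 4), 3 to 17 for siCCAR2 and 8 to 261 for siZNF282. CALCOCO1 in ethanol ranged from −0.54 to −0.37 (adjusted p = 0.0037 to 0.074), ZNF282 in dex from −0.92 to −0.75 (adjusted p = 0.0078 to 0.11), and the size from −0.12 to −0.0684 for siCoCoA and −0.13 to −0.0828 for siZNF282. Where 1 array was left in a siZNF282 group, it was assumed to vary like the other groups. Over all fits 226 of 275 named gene values and 38 of 101 list calls kept their side of the threshold. For genes near background, the signal over background limits the size of change that the arrays can show.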

Other observations

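The list tests were fixed beforehand, and single genes outside the called lists were chosen only after the result was seen. In ethanol, without dex, the interferon list was higher in 19 of 26 genes in siCCAR1 cells (20 adjusted over the list alone, median 1.66, adjusted p = 1.98e-19, or adjusted p = 0.18 with an estimated correlation). It was higher in all 26 in siCoCoA (median 3.59, adjusted p = 1.63e-51), siCCAR2 (3.72, adjusted p = 2.59e-50) and siZNF282 cells (5.59, adjusted p = 4.14e-45). In siCCAR1 cells sterol synthesis genes were higher in 5 of 16 (8 adjusted over the list alone, adjusted p = 0.0072, or adjusted p = 0.18 with an estimated correlation). Among them were TM7SF2 (0.98 ± 0.13), SC5D (0.59), MVD (0.55) and SQLE (0.47), which all act in cholesterol synthesis. The p53 targets were higher in 7 of 22 (9, with 2 lower, adjusted over the list alone, adjusted p = 8.69e-04, or adjusted p = 0.18 with an estimated correlation), led by GADD45A (1.11). Inflammatory genes were lower in 8 of 24 with 1 higher (adjusted p = 2.94e-05, or adjusted p = 0.13 with an estimated correlation). So were metallothioneins in 3 of 6 (adjusted p = 9.04e-04, or adjusted p = 0.18 with an estimated correlation) and GR induced genes in 7 of 33 with 1 higher (adjusted p = 0.014, or adjusted p = 0.18 with an estimated correlation; not called without siCCAR1 ethanol array 1). Cell cycle genes were lower in 8 of 33 with 1 higher (11 and 1 adjusted over the list alone, adjusted p = 5.09e-06, or adjusted p = 0.33 with an estimated correlation), with MCM5 at −0.93. In siCoCoA cells cell cycle genes were lower in 20 of 33 (26 adjusted over the list alone, adjusted p = 1.33e-12, or adjusted p = 0.28 with an estimated correlation). GR induced genes were higher in 10 of 33 with 1 lower (12 and 2 adjusted over the list alone, adjusted p = 0.014, or adjusted p = 0.28 with an estimated correlation), with TXNIP at 1.26, KLF9 at 0.99 and ENC1 at −0.94.

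In siCCAR2 cells in ethanol immediate early genes were higher in 4 of 12 (adjusted p = 0.0063), matrix genes in 6 of 20 (adjusted p = 0.0068, or adjusted p = 0.052 with an estimated correlation). Inflammatory genes were higher in 8 of 24 with 1 lower (10 and 1 adjusted over the list alone, adjusted p = 1.90e-04, or adjusted p = 0.052 with an estimated correlation). Cell cycle genes were lower in 5 of 33 with 1 higher (7 and 1 adjusted over the list alone, adjusted p = 0.021, or adjusted p = 0.76 with an estimated correlation), with the cyclin CCNE1 at −1.42; this call was lost without siCCAR2 ethanol array 3 or 4 or siNS ethanol array 2 (medians of −0.20, −0.16 and −0.18, against −0.20). The p53 targets were called higher with 3 of 22 genes higher and 3 lower (8 and 3 adjusted over the list alone, adjusted p = 0.040, or adjusted p = 0.46 with an estimated correlation), and 7 of 10 fits that left out 1 array lost the call. In siZNF282 cells in ethanol GR induced genes were higher in 15 of 33 with 1 lower (17 and 1 adjusted over the list alone, adjusted p = 6.44e-05), among them IGFBP1 (2.44), TXNIP (1.82), the iron carrier LCN2 (1.58) and SPSB1 (1.56). Metallothioneins were higher in 3 of 6 (adjusted p = 0.0030, or adjusted p = 0.12 with an estimated correlation), with MT2A at 2.09 and MT1G at 2.00. Stress genes of the ER and of amino acid supply were higher in 11 of 24 and lower in 5 (adjusted p = 0.032, or adjusted p = 0.12 with an estimated correlation): ATF3 (1.83), VLDLR (1.63) and the stress factor DDIT3 (1.53) rose, and the serine synthesis enzyme PHGDH fell (−0.97). This call and the next were lost without siZNF282 ethanol array 3. Ion and water transport genes were higher in 5 of 15 with 1 lower (7 and 2 adjusted over the list alone, adjusted p = 0.033, or adjusted p = 0.20 with an estimated correlation), as for the carbonic anhydrase CA12 (1.45) and the water channel AQP3 (1.31). Inflammatory genes were higher in 15 of 24 (16 adjusted over the list alone, adjusted p = 1.26e-09) and matrix genes in 10 of 20 with 2 lower (adjusted p = 8.74e-04). Immediate early genes were higher in 4 of 12 with 1 lower (6 and 1 adjusted over the list alone, adjusted p = 0.0015), and Wnt targets in 5 of 15 with 1 lower (6 and 1 adjusted over the list alone, adjusted p = 0.014, or adjusted p = 0.080 with an estimated correlation). Cell cycle genes were lower in 13 of 33 (adjusted p = 5.41e-04, or adjusted p = 0.40 with an estimated correlation), with BUB1B at −1.46. Ribosomal protein genes were lower in 7 of 23 (adjusted p = 0.029, or adjusted p = 0.13 with an estimated correlation), and were not called without siZNF282 ethanol array 2.

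Alveolar type II, apoptosis, receptor and coregulator, hypoxia and housekeeping lists were not called in any of the 17 comparisons. The paired fit with a replicate block called the hypoxia list higher with dex in siNS (adjusted p = 0.042, or adjusted p = 0.094 without the block) and siCCAR2 cells (adjusted p = 0.017, or adjusted p = 0.071 without it). Among their members LAMP3, which interferon also induces, was higher in 7 of 8 depletions and B2M, an HLA class I subunit that interferon induces, in all 8 (0.87 to 2.71). GAPDH was at −0.47 and PPIA at −0.93 in siZNF282 cells in dex. SFTPD, a surfactant protein, rose by 0.78 and the anti-apoptotic MCL1 by 1.04 with dex in siNS cells. PFKFB4 was 1.12 in siCCAR1 cells in dex, and the receptor RXRA was −0.82 in siCCAR2 cells in ethanol. Markers of other cell types had too few tested genes for a list test (endothelial 2, leukocyte 3, fibroblast 4). CD68, which A549 cells themselves showed at group means of 8.17 to 12.9, was called in 6 of 8 depletions, by up to 3.77 in siZNF282 cells in dex, and CD14 in 4, by up to 0.86. COL1A1 (0.63 in siCCAR2 cells in dex), THY1 (−0.76 in siZNF282 cells in ethanol), TEK (0.59 in siZNF282 cells in ethanol), DCN (0.67 with dex in siCoCoA cells) and CD79A (0.64 with dex in siCCAR2 cells) were called in 1 to 4 comparisons, and ESAM and LUM in none.

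Of the 11 called differences in siCCAR1 cells 7 were smaller responses, 3 were called in siNS cells alone and 1 was opposite. Of the 26 in siZNF282 cells 15 were responses called in depleted cells alone, 7 in siNS cells alone, 2 were smaller and 2 opposite. Most of the 15 were called against siNS in ethanol and lay near siNS in dex, so they need not be new dex responses. The genes past the threshold that the rule for named genes left out, named after their values were seen, were in siCCAR1 cells GADD45A (−1.06), RRAD (−1.28), CDH16 (−1.20), TUBA3E (−1.14), CILP (−1.08) and TDRD9 (−0.87), and in siCCAR2 cells ARMCX1 (0.93), PHLDA1 (0.82) and CABYR (0.72); a further 18 in siZNF282 cells are not named.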
